A study of Mus musculus with 12 samples.

How the data were processed

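Bulk RNA sequencing libraries of microglia from the brain (MG) and of macrophages from the dura mater (DM) were analysed in 4 groups of 3 libraries, 12 in all: MG and DM of control mice, which received phosphate-buffered saline (PBS), and MG and DM of mice examined 2 days after infection with group B streptococcus (GBS). All mice carried a tamoxifen-inducible Cre recombinase under the Mrc1 gene together with a Tomato reporter, and per the labels they received tamoxifen 8 weeks before infection. Per the labels' protocols, brain and dura were dissected apart, digested with collagenase IV, passed over Percoll and stained with antibodies, and libraries were made with the SMART-Seq Stranded kit. The antibodies used to sort the cells and the sort gates are not given in the sources used here.

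The deposited table holds the authors' read counts per gene, as whole numbers that were not normalized, for 43346 genes, of which 42462 have a symbol. The submitters' processing notes name bcl2fastq 2.19, cutadapt, STAR 2.5.2b, DESeq2 and the mouse genome build mm10, without roles. The program that counted the reads, its strand setting and the annotation release are not given in the sources used here. Reads of near-identical genes (H2-Q6 and H2-Q7, Tgtp1 and Tgtp2, Ifit3 and Ifit3b, Hspa1a and Hspa1b, the alpha globins, and the histone genes) could have been split or dropped by the counting, so values of such genes are uncertain, as are those of overlapping genes and, with the strand setting not given, of antisense partners. No entry of the table was a total or a class of unassigned reads, and no column was left unused. Gene positions and gene types were looked up by gene identifier in the GENCODE M21 annotation, which uses the same build under its other name, GRCm38.

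Genes were tested in edgeR 4.0.16 under R 4.3.3. Genes with low counts were removed with filterByExpr, which left 16889 genes, library sizes were scaled with the trimmed mean of M values (TMM), and edgeR's quasi-likelihood test with robust estimation was fitted once to all 12 libraries with a mean per group. Contrasts were infected versus control in MG and in DM, DM versus MG in control and in infected mice, and the difference of the infection responses (DM minus MG), which is the interaction of population and infection. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Values are log2 fold changes with their standard errors (SE), and levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD with n = 3. A fold against a group without a single count is a lower bound, computed with 3 counts over the libraries of that group in place of 0.

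The spread between replicates differed strongly between the populations: the common biological coefficient of variation was 0.142 in MG, 0.654 in DM and 0.505 over all libraries. Each pairwise comparison was therefore also fitted to its own 6 libraries, and the difference of responses with limma-voom (limma 3.58.1) with a weight per library, and the count of genes called in both fits is printed beside the total of each comparison. The choice to test with all 12 libraries was kept because it was made before the data were examined, as were the comparisons, the gene lists, the rule for naming genes and most alternatives. The procedure was tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold in each infection comparison. In MG the fit to all 12 libraries recovered 36% of the 2-fold and 85% of the 4-fold changes with 0 false calls, and the fit to 6 libraries recovered 99% and 100% with 9 false calls among 208. In DM the fit to all 12 libraries recovered 48% and 89% but made 156 false calls among 293, whereas the fit to 6 libraries recovered 19% and 74% with 7 false calls among 100. For the difference of responses the fit to all 12 libraries recovered 10.2% of 196 genes changed 2-fold and 68.6% of 194 changed 4-fold, with 15 false calls among 171, and the weighted fit recovered 5.61% and 61.9%, with 9 false calls among 143.

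The gene lists held 647 genes, of which 644 were found. Gbp5, Gbp6 and Ahsp were not analysed here, and Fam26f was matched under its current symbol, Calhm6. The lists were microglia identity, border macrophage identity, MHC class I, MHC class II, type I interferon response, interferon gamma response, inflammatory cytokines, chemokines, NF-kB targets and feedback, bacterial sensing, complement and phagocytic receptors, antimicrobial and oxidative defence, disease-associated microglia, cell cycle, glycolysis and hypoxia, cholesterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, lysosome, immediate early genes and dissociation stress, apoptosis and cell death, and markers of neutrophils, monocytes, T and NK cells, B cells, dendritic cells, mast cells, astrocytes, oligodendrocytes, neurons, endothelial and mural cells, fibroblasts, erythroid cells and choroid plexus. Each list was tested against all other genes with camera at its preset correlation of 0.01 between genes, adjusted over the 34 lists, and again with the correlation estimated from the data. Genes were named by rule: in each pairwise comparison the 8 largest rises and 8 largest falls among called genes with an absolute log2 fold change of at least 1, a mean of at least 10 CPM in the higher group and no overlap between the groups; in the difference of responses the 6 largest in each direction; up to 4 members of each list with the smallest p; and in every comparison Mrc1, Lyve1, P2ry12, Tmem119 and Cx3cr1. Mpo and Prtn3, and the values of single libraries given for other genes, lie outside this rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

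The libraries held 10974095 to 53846961 counts, so that 3 counts corresponded to 0.0538 CPM in the deepest library and 0.291 CPM in the shallowest. Such floors cover counting error only, since the reads carried no molecular identifiers. Per the series design 3 control and 3 infected mice were used, so that p-values rest on 3 mice per state, and brain and dura libraries of 1 state may come from the same mice, although the labels do not say that a shared number marks a shared mouse. Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom without and with weights, a test against a fold change of 1.5 (glmTreat), a replicate block, other list tests (fry, estimated correlation), and leaving out each library in turn. A fit without DM infected libraries 1 and 3, which alone held high levels of granulocyte precursor transcripts, and a fit without ribosomal RNA-like features were added after the values were seen. No library was left out of the main results.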

Results

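The transcriptomes of microglia (MG), the resident macrophages of the brain parenchyma, were compared with those of dural macrophages (DM), which occupy the outermost layer of the meninges. Both were taken from control mice and from mice infected 2 days earlier with group B streptococcus (GBS), a cause of bacterial meningitis, with 3 libraries in each of the 4 groups. Replicates 1 to 3 held 20808824, 53846961 and 38926839 counts in MG of control mice and 37769582, 40430910 and 31195643 in MG of infected mice. In DM they held 24627561, 30568673 and 24760709 counts in control mice and 10974095, 24332260 and 51021846 in infected mice. Between 20497 and 21838 genes had at least 1 count in MG libraries, and between 16809 and 20066 in DM libraries. Features resembling ribosomal RNA took 12.2 to 13.8% of counts in MG of control mice and 15.2 to 17.8% in MG of infected mice. In DM they took 20.5 to 24.1% in control mice and 24.7 to 25.5% in infected mice. Mitochondrial transcripts took 3.19 to 4.64% of counts in MG and 12 to 13.8% in DM. The ribosomal RNA-like features were Gm23935, Gm26917, Gm42418, mt-Rnr1 and mt-Rnr2, counted together with Rn7sk and Rpph1, which are not ribosomal. The mitochondrial genes mt-Rnr1 and mt-Rnr2 enter both shares. In MG mt-Rnr1 took 0.894 to 1.35% and mt-Rnr2 1.98 to 2.84% of counts. They took 3.14 to 3.85% and 7.59 to 8.82% in DM, so the higher shares in DM are largely the same reads.

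The libraries carried the transcripts of the population named in their labels. The microglial purinergic receptor gene P2ry12 (chromosome 3, 59216272 to 59262871, minus strand of GRCm38) stood at 2320 ± 262 CPM in MG and 52.9 ± 11.7 CPM in DM of control mice (SD, n = 3). The microglial membrane protein gene Tmem119 (chromosome 5, 113793729 to 113800516, minus strand) stood at 1110 ± 62.5 and 21.3 ± 5.17 CPM. The mannose receptor gene Mrc1 (chromosome 2, 14229392 to 14332057, plus strand), which drove the Cre recombinase in these mice, stood at 442 ± 121 CPM in DM and 8.33 ± 0.728 CPM in MG. The first principal component of log2 CPM held 57.4% of the variance and separated MG from DM. The second held 10.5% and separated DM of control mice from DM of infected mice. Replicates correlated at r = 0.985 to 0.991 in MG and at r = 0.87 to 0.901 in DM, across genes, which are not independent replicates.

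**Figure D1:**
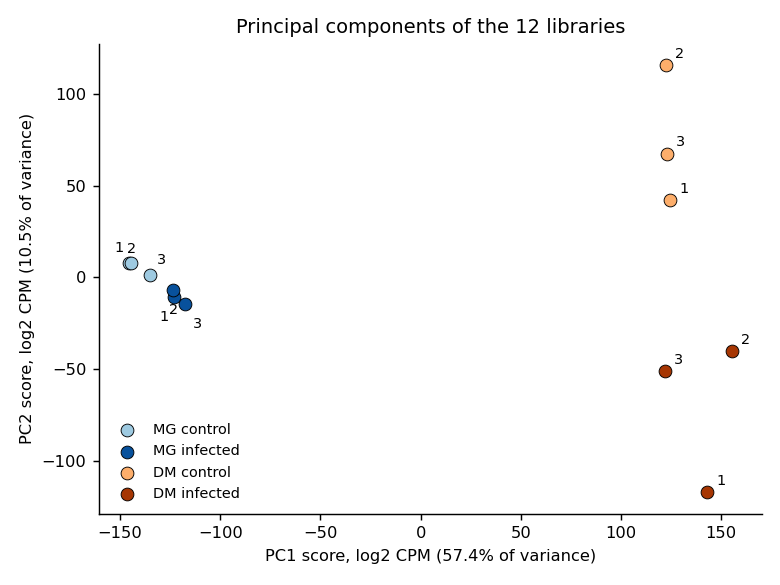
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM, with points coloured by group and the replicate number beside each point. MG libraries lie between -145.4 and -117.5 on the first axis and DM libraries between 121.7 and 155.5, and on the second axis DM of control mice lie between 42.2 and 115.6 and DM of infected mice between -117.4 and -40.3.

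The first comparison asked how dural macrophages differ from microglia in control mice. Transcripts of MHC class II antigen presentation were abundant in DM and scarce in MG. The invariant chain gene Cd74 (chromosome 18, 60803848 to 60812652, plus strand) stood at 7560 ± 368 CPM in DM and 84.6 ± 9.67 CPM in MG, 89.4-fold apart (log2 fold change 6.48, SE 0.22, adjusted p = 1.87e-10). The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 were 105-fold, 94.6-fold and 113-fold higher in DM. DM also held more Apoe, a lipid carrier (12900 ± 1260 against 303 ± 113 CPM), Lyz2, the lysozyme of myeloid cells (22.2-fold), and Igf1, a growth factor (278-fold). MG held more of the microglial transcription factor gene Sall1 (1220 ± 34.2 against 3.95 ± 2.09 CPM) and of the fractalkine receptor gene Cx3cr1 (11.4-fold).

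Of 16889 genes tested, 7284 differed between the populations in control mice, 3702 higher in DM and 3582 higher in MG. The fit to the 6 libraries of control mice called 7183, and 6496 were called in both. The groups did not overlap for 10177 genes (60.3%, where chance gives 10%). The largest differences were of genes almost without counts in the other population. In DM they included H19, an imprinted non-coding RNA (117 ± 47.4 CPM, at least 4640-fold higher), the anti-inflammatory cytokine gene Il10 (at least 599-fold), the matrix proteoglycan gene Lum, which is among the listed fibroblast markers (at least 557-fold), and the proton pump gene Atp6v0d2 (at least 520-fold). The C-type lectin genes Cd209f and Cd209g (log2 fold changes 11.85, SE 0.60, and 12.35, SE 1.04), the phospholipase gene Pla2g2d (11.81, SE 0.37) and the chemokine gene Cxcl1 (11.49, SE 1.28) followed. In MG they were Upk1b, a uroplakin (at least 1580-fold higher than in DM), Chst8 (at least 345-fold), Hspb3 (at least 279-fold) and Gp9 (at least 271-fold). Sall3, Ajm1, Ecscr and Naalad2 had log2 fold changes of -11.87 (SE 0.33), -10.23 (SE 0.83), -9.82 (SE 0.67) and -9.63 (SE 1.45) for DM against MG.

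All 18 microglia identity genes were lower in DM than in MG (18 adjusted over the list alone), among them P2ry13 (27.1-fold), Selplg (12.5-fold) and P2ry12 (43.8-fold). Of 20 border macrophage identity genes 19 were higher (19 adjusted over the list alone), among them the carbonyl reductase gene Cbr2 (1040-fold), Ms4a7 (372-fold), the endocytic adaptor gene Dab2 (52.9-fold) and Mrc1 (53.2-fold). Both lists were called (adjusted p = 3.96e-15 and 1.64e-13), but not with an estimated correlation (adjusted p = 0.0635 and 0.0918). Of 10 MHC class II genes 9 were higher in DM (9 adjusted over the list alone). This was the 1 list of 25 called whose call held with an estimated correlation (adjusted p = 0.0406).

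Inflammatory and interferon programmes also stood higher in DM of control mice. Higher were 19 of 20 NF-kB targets and feedback genes (19 adjusted over the list alone), with Tnip3 335-fold, Traf1 65.7-fold and Birc3 5.94-fold. Of 21 chemokines 17 were higher and 0 lower (19 and 1 adjusted over the list alone), with Ccl8 1010-fold and Cxcl2 742-fold. Of 17 MHC class I genes 14 were higher (14, with 1 lower, adjusted over the list alone), with the transactivator gene Nlrc5 6.98-fold. Of 30 type I interferon response genes 23 were higher and 1 lower (23 and 1 adjusted over the list alone), with Slfn5 17.8-fold. Of 19 interferon gamma response genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with the GTPase gene Gbp2 6.94-fold. All 30 cytosolic ribosomal proteins were higher (30 adjusted over the list alone), with Rpl28 3.94-fold. With an estimated correlation the adjusted p of these 6 lists were 0.0635, 0.0635, 0.21, 0.266, 0.0951 and 0.155.

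The remaining lists ran in part both ways. Of 18 inflammatory cytokines 11 were higher in DM and 4 lower, and the interleukin-1 beta gene Il1b was 310-fold higher (861 ± 178 against 2.78 ± 0.557 CPM). Of 24 complement and phagocytic receptor genes 14 were higher, such as the scavenger receptor gene Cd36 (128-fold), and 9 lower. Of 28 bacterial sensing genes 12 were higher and 10 lower, and of 20 antimicrobial and oxidative defence genes 11 and 4, with the oxidase subunit gene Cybb 30-fold higher. The counts higher and lower were 11 and 6 of 21 disease-associated microglia genes, 10 and 6 of 24 glycolysis and hypoxia genes, and 8 and 1 of 19 cholesterol biosynthesis genes. They were 16 and 1 of 29 oxidative phosphorylation genes, 11 and 3 of 21 apoptosis genes, and 4 and 8 of 22 immediate early genes. Of 30 cell cycle genes 15 were higher and 1 lower, with Mki67 8.17-fold higher. Of 25 lysosome genes 3 were higher and 16 lower, among the latter the protease genes Ctsd (7.99-fold) and Ctsl (4.68-fold).

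Among these lists oxidative phosphorylation (adjusted p = 0.000233, and 0.266 with an estimated correlation), cell cycle (0.0179, and 0.592) and cholesterol biosynthesis (0.0376, and 0.444) were called as higher in DM. So were antimicrobial defence (0.00041, and 0.115), cytokines (0.0126, and 0.202), apoptosis (0.0229, and 0.236), disease-associated microglia (0.0239, and 0.383) and complement (0.0389, and 0.512). Lysosome genes were called as lower (0.000355, and 0.37). Adjusted over the list alone, the counts higher and lower in DM were 12 and 4 for cytokines, 14 and 9 for complement, 12 and 11 for bacterial sensing, and 11 and 4 for antimicrobial defence. They were 11 and 6 for disease-associated microglia, 10 and 6 for glycolysis, 9 and 1 for cholesterol, and 16 and 1 for oxidative phosphorylation. They were 11 and 3 for apoptosis, 4 and 8 for immediate early genes, 18 and 1 for cell cycle, and 3 and 18 for lysosome.

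Markers of other cell types stood higher in DM libraries as well, and how much such cells add to the differences from MG was not tested. Higher in DM were 12 of 13 B cell markers (Ms4a1 898-fold), 17 of 18 T and NK cell markers (Cd4 98.8-fold) and 13 of 13 fibroblast markers (Col6a2 1140-fold, Mgp 866-fold). Higher were also 12 of 14 dendritic cell markers with 1 lower (Ccr7 160-fold), 12 of 18 monocyte markers with 1 lower (Plac8 23.8-fold) and 8 of 10 mast cell markers (Cpa3 86.2-fold). Adjusted over the list alone these counts were 12, 17, 13, 13, 12 and 9. The B cell marker Cd79a stood at 105, 113 and 159 CPM in the 3 DM control libraries and at no more than 0.422 CPM in any MG library. The fibroblast marker Col1a1 stood at 251, 133 and 193 CPM in DM of control mice. Higher and lower in DM were 2 and 3 of 15 neutrophil markers, 4 and 1 of 10 astrocyte markers, 3 and 2 of 6 oligodendrocyte markers, and 4 and 0 of 10 neuron markers. They were 5 and 2 of 12 endothelial and mural markers, 0 and 0 of 6 erythroid markers, and 0 and 2 of 8 choroid plexus markers.

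The next comparison asked how microglia respond to infection. In MG, 20 of 30 type I interferon response genes, 13 of 30 cell cycle genes and 5 of 24 complement and phagocytic receptor genes rose after GBS. The complement component gene C4b (chromosome 17, 34728380 to 34743882, minus strand) rose 19.3-fold, from 5.04 ± 2.98 to 97.4 ± 38.9 CPM (log2 fold change 4.27, SE 0.42, adjusted p = 0.000369). The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361, minus strand) rose 10.4-fold, from 11.3 ± 3 to 118 ± 53.8 CPM (adjusted p = 0.00287). Plac8, a gene of monocytes and other leukocytes (chromosome 5, 100553725 to 100572245, minus strand), rose 8.76-fold, from 1.1 ± 0.0807 to 9.59 ± 0.785 CPM (adjusted p = 5.59e-06). The interferon-inducible GTPase gene Gbp2 rose from 7.67 ± 2.38 to 29.2 ± 1.53 CPM, and the interferon signalling gene Stat2 from 37.9 ± 6.82 to 104 ± 17.3 CPM. P2ry12 stood at 2320 ± 262 CPM in control and 1220 ± 360 CPM in infected mice, with an adjusted p of 0.14 in the fit to all libraries and 0.0132 in the fit to MG alone.

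**Figure D2:**
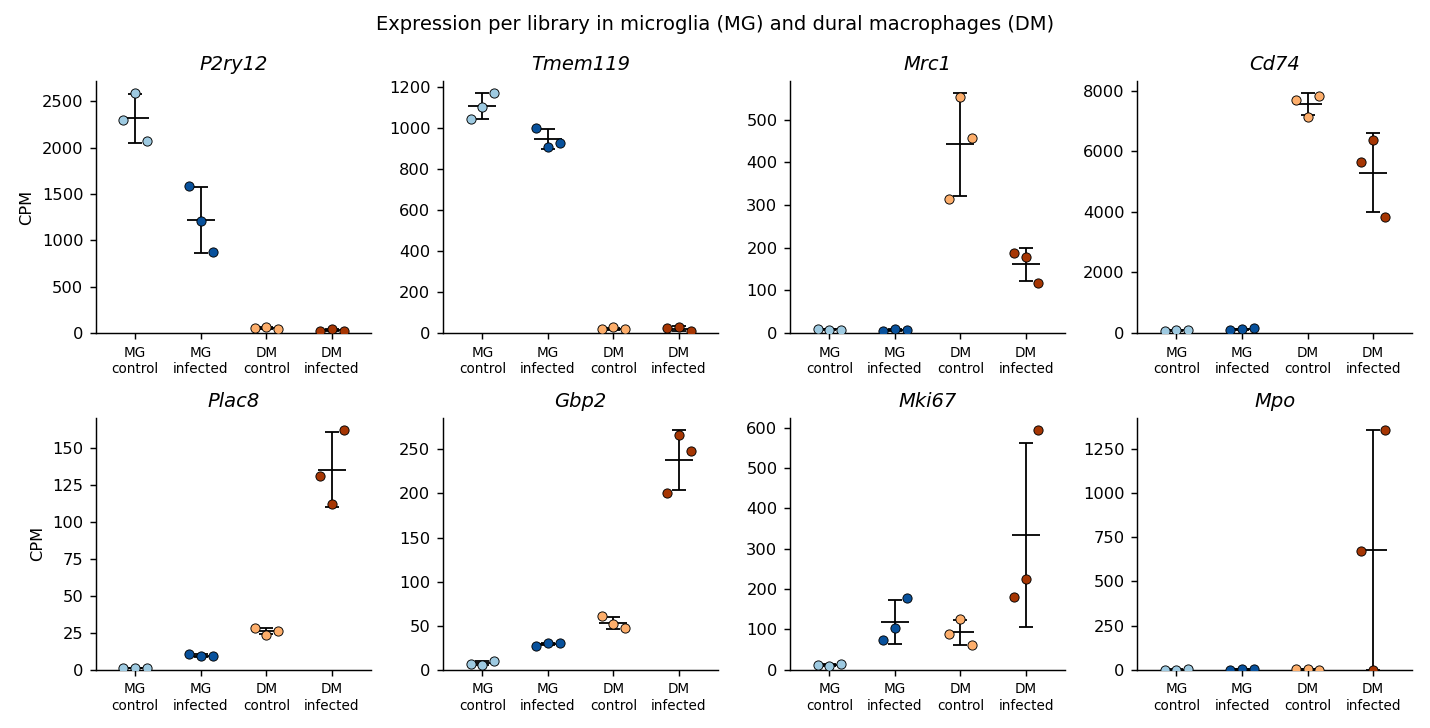
CPM of 8 genes in each of the 12 libraries, with 1 point per library, a horizontal line at the group mean and error bars of 1 SD (n = 3), on linear axes that start at 0. Mean P2ry12 is 2320 and 1220 CPM in the MG groups and mean Plac8 is 26 and 135 CPM in the DM groups, while Mpo is high in DM infected libraries 1 and 3 alone.

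In all, 258 genes changed in MG, of which 234 rose and 24 fell. The fit to the 6 MG libraries called 1811 (1058 and 753), and 253 were called in both. The groups did not overlap for 4690 genes (27.8%, where chance gives 10%). Beside C4b, Mki67 and the DNA topoisomerase gene Top2a (10-fold), the largest rises were of Uhrf1, which maintains DNA methylation through replication (13.6-fold), and of Cd244a, a receptor of the SLAM family (11.6-fold). The kinetochore gene Kntc1 (16.3-fold), the cell cycle transcription factor gene E2f8 (11.1-fold) and the histone gene Hist1h3b (10.7-fold) also rose. The 3 falls of at least 2-fold were of the immediate early transcription factor gene Egr3 (31 ± 1.74 to 14 ± 2.61 CPM), the adaptor gene Cass4 (63.3 ± 6.04 to 29.3 ± 4.31 CPM) and the zinc finger gene Zfp691 (105 ± 13.6 to 52.2 ± 12 CPM). The count of 258 was 102 without MG control 1, 97 without MG control 2, 164 without MG control 3 and 110 without MG infected 3, and each of these 3 falls lost its call without at least 1 of those libraries.

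Of 30 type I interferon response genes, 20 rose in MG and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.52. The list was called (adjusted p = 1.12e-49, and 0.0251 with an estimated correlation). Ifi204, of a family of DNA sensors, rose 6.11-fold, Slfn5 5.2-fold and Rtp4 4.96-fold. Of 19 interferon gamma response genes 8 rose (9 adjusted over the list alone), among them Ly6a (6.37-fold), Gbp7 (2.23-fold) and Gbp3 (2.05-fold), and the list was called (adjusted p = 1.32e-13, and 0.0106 with an estimated correlation). Of 17 MHC class I genes 2 rose (3 adjusted over the list alone), Nlrc5 (3.51-fold) and the peptide transporter gene Tap1 (1.66-fold). This list was called (adjusted p = 1.93e-05), but not with an estimated correlation (adjusted p = 0.407). Of 10 MHC class II genes 2 rose (5, with 1 lower, adjusted over the list alone), the class II transactivator gene Ciita (2.64-fold) and H2-Aa (1.7-fold).

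Of 30 cell cycle genes, 13 rose in MG and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 2.24. The list was called (adjusted p = 6.97e-32), but not with an estimated correlation (adjusted p = 0.0673). The replication helicase genes Mcm5 and Mcm6 rose 4.46-fold and 3.54-fold. Mki67 stood at 72.5, 104 and 177 CPM in infected MG libraries 1, 2 and 3 and at 12.1, 8.03 and 13.9 CPM in the controls. Beside this rise, the granulocyte precursor gene Mpo stayed at or below 3.793 CPM in every MG library.

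Of 24 complement and phagocytic receptor genes 5 rose in MG (9 adjusted over the list alone), with the Fc receptor gene Fcgr4 4.47-fold, the scavenger receptor gene Msr1 6.94-fold and the properdin gene Cfp 2.91-fold higher. The list was called (adjusted p = 2.42e-11), but not with an estimated correlation (adjusted p = 0.0981). Of 18 monocyte markers 4 rose (10 adjusted over the list alone), among them Plac8, Cd244a and Ms4a4c (5.78-fold). This list was called (adjusted p = 8.68e-09, and 0.0251 with an estimated correlation), and its summed level was 111 to 128 CPM in MG control libraries and 196 to 295 CPM in infected ones. Of 15 neutrophil markers Il1r2 and Mmp8 rose (2 adjusted over the list alone), and the list was called (adjusted p = 0.000408, and 0.407 with an estimated correlation). Of 18 T and NK cell markers the granzyme genes Gzma and Gzmb rose (6, with 2 lower, adjusted over the list alone), and of 14 dendritic cell markers Naaa (4 adjusted over the list alone).

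Of 18 inflammatory cytokines 2 rose in MG (3, with 1 lower, adjusted over the list alone), Il1b (3.73-fold, to 10.4 ± 3.43 CPM) and the gene of its receptor antagonist, Il1rn (5.62-fold). Of 20 NF-kB genes Bcl3 rose (4.72-fold; 1 adjusted over the list alone). Of 28 bacterial sensing genes the lectin receptor gene Clec4e (10.1-fold) and the formyl peptide receptor gene Fpr2 (19.1-fold, to 1.22 ± 0.276 CPM) rose (4 adjusted over the list alone; list adjusted p = 0.0181, and 0.268 with an estimated correlation). Of 21 disease-associated microglia genes Lgals3 and Spp1 rose (7, with 1 lower, adjusted over the list alone), and of 20 antimicrobial genes Cybb (4 adjusted over the list alone). Of 30 cytosolic ribosomal proteins Rps2 rose (1 adjusted over the list alone; list adjusted p = 1.96e-05, and 0.677 with an estimated correlation).

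Of 18 microglia identity genes 0 passed over all genes in MG, while 5 fell adjusted over the list alone and 10 fell in the fit to MG libraries. The list as a whole was lower (median log2 fold change -0.36, adjusted p = 1.03e-16), but not with an estimated correlation (adjusted p = 0.0503). In control and infected mice P2ry13 stood at 890 ± 45.9 and 545 ± 65 CPM, Gpr34 at 983 ± 54.2 and 476 ± 189 CPM, and Cx3cr1 at 4210 ± 60.2 and 3270 ± 259 CPM. Tmem119 stood at 1110 ± 62.5 and 945 ± 49.6 CPM. Of 22 immediate early genes 2 fell, Junb (1.72-fold) and Zfp36 (1.59-fold), with 3 higher and 8 lower adjusted over the list alone (list adjusted p = 1.45e-06, and 0.417 with an estimated correlation). Of 20 border macrophage identity genes Siglec1, Clec4n and Cd38 rose and Igfbp4 fell (5 and 2 adjusted over the list alone). Mrc1 (8.33 ± 0.728 and 6.62 ± 1.68 CPM) and Lyve1 (0.284 ± 0.159 and 0.216 ± 0.278 CPM) did not pass. Not a single gene passed among chemokines, glycolysis, cholesterol biosynthesis, oxidative phosphorylation, lysosome and apoptosis genes. The fit to MG libraries called 2 higher and 4 lower chemokines, 3 and 4 apoptosis genes, 3 and 1 lysosome genes, 1 and 2 glycolysis genes, 1 and 0 cholesterol genes and 0 oxidative phosphorylation genes. In the fit to all libraries 0 genes passed among markers of B cells, mast cells, astrocytes, oligodendrocytes, neurons, endothelium, fibroblasts, erythroid cells and choroid plexus, and in the fit to MG libraries 2 B cell, 2 erythroid, 1 neuron and 1 endothelial marker fell.

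The same question, the response to infection, was asked of dural macrophages. In DM, most genes of the type I interferon response and of MHC class I rose, and 8 of 20 border macrophage identity genes and 12 of 22 immediate early genes fell. Gbp2 rose 4.48-fold, from 53.2 ± 6.81 to 238 ± 34.2 CPM (log2 fold change 2.16, SE 0.20, adjusted p = 0.000195), and Plac8 5.2-fold, from 26 ± 2.16 to 135 ± 25.3 CPM (adjusted p = 4.96e-05). The monocyte-attracting chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799, plus strand) rose 4.69-fold, from 121 ± 33.4 to 567 ± 176 CPM (adjusted p = 0.000537). Mrc1 fell 2.75-fold, from 442 ± 121 to 161 ± 38.9 CPM (log2 fold change -1.46, SE 0.23, adjusted p = 0.00306), and the scavenger receptor gene Stab1 2.31-fold, from 1310 ± 197 to 568 ± 140 CPM. Lyve1, a hyaluronan receptor gene of a subset of border macrophages, stood at 61.1 ± 22.8 and 81.8 ± 39.7 CPM and did not pass (adjusted p = 0.65).

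In all, 1529 genes were called in DM by the fit to all 12 libraries, of which 698 rose and 831 fell. In the simulated data this fit made 156 false calls among 293 in DM. The fit to the 6 DM libraries called 355 (186 and 169), and 351 were called in both. Among the genes that the naming rule picked for DM, 91 were called by the fit to all libraries. Of these 32 lost their call in the fit to DM libraries, and 62 with limma-voom with sample weights. Not every gene named below is marked for this. The groups did not overlap for 3306 genes (19.6%, where chance gives 10%). Among the largest changes called in both fits was a rise of Cd5l, a secreted macrophage protein (55.9-fold, to 39.1 ± 43.1 CPM). Falls called in both were of the metalloprotease gene Adam33 (8.4-fold), the growth factor gene Pdgfa (7.77-fold, from 45.9 ± 22.1 to 5.88 ± 2.34 CPM) and Ms4a14 (6.81-fold). Siglech (chromosome 7, 55768178 to 55778925, plus strand; 5.34-fold), the eosinophil-attracting chemokine gene Ccl24 (5.28-fold) and the urea transporter gene Slc14a1 (5.03-fold) fell in both fits too. Rises of S100a8 (689-fold), Ngp (375-fold), Lcn2 (279-fold), Chil3 (111-fold), Prg4 (53-fold), Hist1h3c (28-fold) and Stil (26.1-fold) were not called in the fit to DM libraries, nor were falls of Tle2 (5.53-fold) and Fhad1 (4.99-fold). The count of 1529 was 963 without MG control 2 and 994 without MG infected 1, in fits to more genes (17859 and 17852).

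Of 30 type I interferon response genes 27 rose in DM and 0 fell (30 and 0 adjusted over the list alone; 27 in the fit to DM libraries), with a median log2 fold change of 1.79. Among them were Ifit1 (5.11-fold), Ifit2 (5.7-fold) and Rtp4 (4.74-fold). Of 17 MHC class I genes 14 rose and 0 fell (14 adjusted over the list alone; 13 in the fit to DM libraries). Among them were Tap1 (2.98-fold), the immunoproteasome gene Psmb10 (2.87-fold), H2-T22 (2.69-fold) and H2-T23 (2.29-fold). These 2 lists were called (adjusted p = 5.02e-31 and 1.53e-18), but not with an estimated correlation (adjusted p = 0.0908 for both). Of 19 interferon gamma response genes 12 rose (16 adjusted over the list alone; 11 in the fit to DM libraries), including Ly6a (9.13-fold), the GTPase gene Igtp (3.83-fold) and Gbp3 (2.63-fold). This list was called in either way (adjusted p = 1.03e-20, and 0.00245 with an estimated correlation). Of 10 MHC class II genes 0 passed (0 adjusted over the list alone). Cd74 stood at 7560 ± 368 and 5290 ± 1300 CPM, and the list was lower (adjusted p = 0.0106, and 0.187 with an estimated correlation).

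Of 20 border macrophage identity genes 8 fell in DM and 0 rose (10 fell and 1 rose adjusted over the list alone), among them Igfbp4 (2.78-fold), Cd209f (3.26-fold), Stab1 and Mrc1. Of 18 microglia identity genes, which stood lower in DM than in MG, 7 fell (9 adjusted over the list alone), among them Siglech, Gpr34 (3.54-fold) and Mef2c (1.97-fold). Sall1 (chromosome 8, 89027235 to 89044162, minus strand) stood at 3.95 ± 2.09 CPM in control mice and had 0 counts in infected mice, at least 109-fold lower. Of 22 immediate early genes 12 fell and 0 rose (15 adjusted over the list alone), such as Ier3 (2.71-fold), Jun (1.99-fold) and Atf3 (1.82-fold). Of 20 NF-kB genes 6 fell and 0 rose (9 adjusted over the list alone), such as Tnip3 (3.28-fold), Cd83 (2.08-fold) and Rel (1.59-fold). In the fit to DM libraries 6 border macrophage, 5 microglia identity, 8 immediate early and 3 NF-kB genes fell. The summed level of the border macrophage list was 7180, 8520 and 8010 CPM in DM control libraries and 5980, 5460 and 3690 CPM in infected ones, beside which the neutrophil markers summed to 220, 144 and 168 and to 989, 397 and 3850 CPM. The 4 lists were called as lower (adjusted p = 1.06e-07, 1.36e-06, 9.96e-09 and 3.62e-07), but not with an estimated correlation (adjusted p = 0.217, 0.187, 0.265 and 0.187). In the fit to all 12 libraries the pattern recognition genes Cd14 (2.39-fold) and Nlrp3 (2.12-fold), the complement receptor gene C3ar1 (2.46-fold) and Igf1 (3.1-fold) fell. The Fc receptor genes Fcgr4 (6.55-fold) and Fcgr1 (2.23-fold) rose in that fit.

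Of 30 cell cycle genes 18 rose and 0 fell in DM (26 adjusted over the list alone; 11 in the fit to DM libraries), among them Mcm5 (4.36-fold), Mcm3 (2.26-fold), Ccna2 (7.67-fold) and Tyms (18.2-fold). The list was called (adjusted p = 1.65e-17), but not with an estimated correlation (adjusted p = 0.187). Mki67 stood at 181, 225 and 595 CPM in DM infected libraries 1, 2 and 3. In the same libraries the granulocyte precursor gene Mpo stood at 674, 0.923 and 1357 CPM and Elane at 89.9, 0 and 315 CPM, against at most 3.294 CPM of Mpo in the DM controls. Of 15 neutrophil markers 3 rose (9 adjusted over the list alone) and 0 did in the fit to DM libraries (list adjusted p = 0.00052, and 0.331 with an estimated correlation). Of 18 monocyte markers 6 rose (8 adjusted over the list alone), Plac8 and Ms4a4c (4.97-fold) among them, and 2 in the fit to DM libraries (list adjusted p = 0.000145, and 0.133 with an estimated correlation). Without DM infected libraries 1 and 3, which leaves 1 infected DM library, 2241 genes were called in DM, of which 777 were among the 1529, and 8 of 30 cell cycle genes rose.

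Of 29 oxidative phosphorylation genes 6 rose in DM (14 adjusted over the list alone; 2 in the fit to DM libraries), such as Cycs (2.21-fold) and Atp5b (1.53-fold). Of 24 glycolysis and hypoxia genes 4 rose and 1 fell (9 and 1 adjusted over the list alone; 2 and 0 in the fit to DM libraries), with Pkm 1.82-fold higher. Both lists were called (adjusted p = 3.62e-07 and 0.00224), but not with an estimated correlation (adjusted p = 0.187 and 0.347). Of 30 cytosolic ribosomal proteins Rps20 rose (1 adjusted over the list alone; 0 in the fit to DM libraries; list adjusted p = 9.67e-09, and 0.433 with an estimated correlation). Of 21 chemokines 3 rose and 4 fell (6 and 8 adjusted over the list alone; 2 and 2 in the fit to DM libraries), with Ccl6 2.52-fold higher and Ccl2 2.08-fold lower. Of 21 apoptosis genes 4 rose and 2 fell (5 and 4 adjusted over the list alone; 2 and 0 in the fit to DM libraries), with the necroptosis effector gene Mlkl 4.46-fold higher. Of 18 T and NK cell markers 3 rose (5 adjusted over the list alone; 2 in the fit to DM libraries), with Gzma 5.51-fold higher.

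Genes that rose and fell in DM numbered 3 and 1 of 18 cytokines (3 and 4 adjusted over the list alone), 3 and 4 of 28 bacterial sensing genes (5 and 5), 3 and 5 of 24 complement genes (7 and 5), and 4 and 1 of 20 antimicrobial genes (4 and 3). In the fit to DM libraries these counts were 0 and 0 for cytokines, 0 and 2 for bacterial sensing, 2 and 3 for complement, and 1 and 0 for antimicrobial genes. They numbered 1 and 2 of 21 disease-associated microglia genes, 2 and 1 of 25 lysosome genes, 0 and 1 of 19 cholesterol genes, and 0 and 1 of 14 dendritic cell markers, and in the fit to DM libraries 0 and 1, 1 and 1, 0 and 0, and 0 and 1. Nrgn rose among neuron markers and Kdr among endothelial markers, neither of them in the fit to DM libraries. Not a single gene passed among B cell, mast cell, oligodendrocyte, fibroblast, erythroid and choroid plexus markers. The erythroid list was called as higher (adjusted p = 0.032, and 0.575 with an estimated correlation). The fibroblast marker Col1a1 stood at 35.4, 127 and 9.69 CPM in the infected DM libraries. Its list was lower (adjusted p = 0.000214, and 0.466 with an estimated correlation) but higher without DM infected 1 and 3 (adjusted p = 0.0194).

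**Figure D3:**
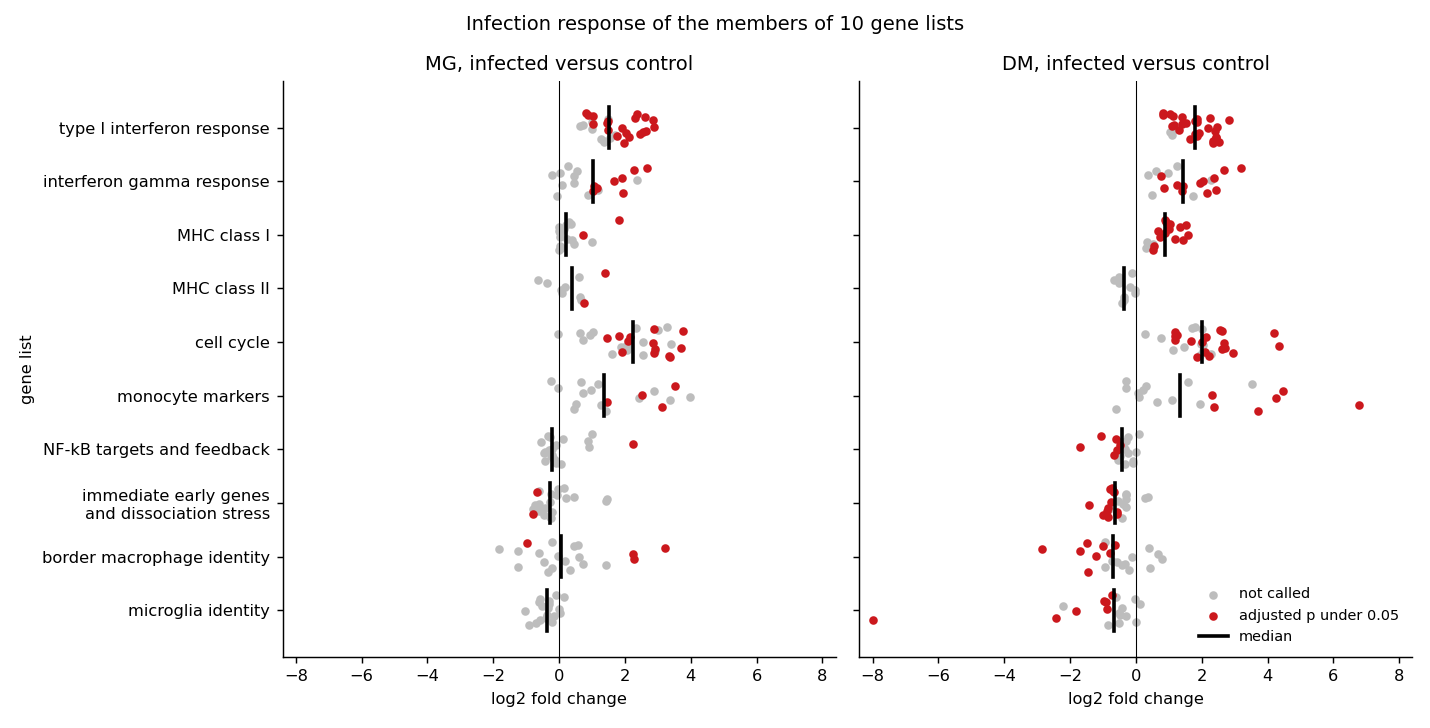
Log2 fold change of each tested member of 10 gene lists, infected versus control, in MG (left) and DM (right), with red points for an adjusted p under 0.05, grey points for genes that did not pass and black bars at list medians. Axes end at 8 on either side, with 1 DM member beyond them (Sall1) drawn at the limit, and the medians of MHC class I genes lie at 0.20 in MG and 0.90 in DM.

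The populations were then compared in infected mice, to ask which differences stand during infection. Cd74 was 41.4-fold higher in DM (5290 ± 1300 against 128 ± 19.9 CPM), H2-Aa 46.4-fold, Mrc1 24.2-fold and Apoe 37.5-fold. P2ry12 (41.9-fold), Tmem119 (44.1-fold) and Cx3cr1 (12.4-fold) were higher in MG. Ccl8 stood at 567 ± 176 CPM in DM and 0.0617 ± 0.0386 CPM in MG. The interferon-inducible GTPase genes Iigp1 and Tgtp2 were 54.7-fold and 20-fold higher in DM, and the class I gene H2-K1 4.51-fold (1560 ± 72.4 against 346 ± 32.3 CPM). MG held more of Tlr7, a receptor for single-stranded RNA (4.37-fold), Itgam, the CD11b chain (4.15-fold), and the cytokine gene Il1a (5.1-fold).

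In infected mice 7603 genes differed, 3725 higher in DM and 3878 higher in MG. The fit to the 6 libraries of infected mice called 6432, and 6169 were called in both. The groups did not overlap for 9955 genes (58.9%, where chance gives 10%). The largest differences toward DM were of Pou2af1, a coactivator of B cells (at least 1870-fold), Pla2g2d (at least 1600-fold), Ccl8 (8780-fold), Ly6d (at least 904-fold) and Fcer2a, the low-affinity IgE receptor (at least 778-fold). Cd209g (at least 727-fold) and the immunoglobulin segments Ighv1-81 (at least 846-fold) and Igkv12-41 (at least 717-fold) followed. B cell markers summed to 745, 2040 and 2040 CPM in infected DM libraries 1, 2 and 3, and to 142 to 173 CPM in infected MG. Whether B cells in the DM libraries brought the B cell and immunoglobulin transcripts named here was not tested. Toward MG they were of Sall1 (at least 22400-fold), Upk1b (at least 761-fold), Ache (at least 363-fold), Aldh1l2 (at least 289-fold) and Jam3 (at least 285-fold). Sall3, Nav3 and Ecscr had log2 fold changes of -13.88 (SE 0.38), -13.59 (SE 0.38) and -9.88 (SE 0.71).

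All 18 microglia identity genes were lower in DM of infected mice (18 adjusted over the list alone), and 17 of 20 border macrophage identity genes (17 adjusted over the list alone) and 9 of 10 MHC class II genes (9 adjusted over the list alone) were higher. Higher were also 17 of 17 MHC class I genes, 26 of 30 type I interferon response genes, 16 of 19 interferon gamma response genes (1 lower) and 17 of 21 chemokines. The same held for 18 of 20 NF-kB genes, 14 of 20 antimicrobial genes (3 lower) and 23 of 29 oxidative phosphorylation genes. Adjusted over the list alone these 7 counts were 17, 27, 16, 17, 18, 14 and 24. Of B cell markers 12 of 13 were higher in DM, with 17 of 18 T and NK cell markers, 13 of 18 monocyte markers, 10 of 13 fibroblast markers and 6 of 15 neutrophil markers (1 lower), and 13, 17, 13, 11 and 6 adjusted over the list alone.

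Of 26 lists called between the populations in infected mice, 8 held with an estimated correlation. They were MHC class II and interferon gamma response (adjusted p = 0.0227 for both), monocyte markers (0.0474), and microglia identity, chemokines, NF-kB targets, antimicrobial defence and T and NK cell markers (0.0475 for each). With an estimated correlation the adjusted p was 0.0547 for MHC class I, 0.0917 for oxidative phosphorylation, 0.101 for border macrophage identity and 0.133 for the type I interferon response.

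Whether the populations differ in their response to infection was tested by the interaction of population and infection. The genes called in the 2 populations overlapped: 98 genes rose in both where 9.67 would do so if the calls were independent. In both 14 fell where 1.18 would, while 6 were called in opposite directions. Both sets of calls come from 1 fit with a shared spread per gene, which can raise the overlap by itself. In separate fits to each population 111 rose in both where 14.1 would, and 56 fell where 8.2 would, with 10 in opposite directions. Genes of higher level are easier to call in either fit. The response itself differed for 112 genes, with 22 higher and 90 lower in DM than in MG. The weighted limma-voom fit called 44 (8 and 36), and 40 were called in both. Over all 16889 genes the 2 responses correlated at r = 0.145 (Spearman's rho 0.217), across genes, which are not independent replicates. Over the 8690 genes with a mean CPM of at least 10 they correlated at r = 0.351 (rho 0.357). Of the 258 genes called in MG 82.2% had the same sign in DM, and of the 1529 called in DM 75.5% had the same sign in MG. The share of equal signs over all genes was not computed.

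Among genes called in both fits, C4b had a lower response in DM than in MG (log2 difference -3.43, SE 0.54, adjusted p = 0.0142), and it stood at 251 ± 44.7 and 449 ± 124 CPM in DM. Il1b (chromosome 2, 129364570 to 129371139, minus strand) had a lower response in DM (-2.29, SE 0.36, adjusted p = 0.0142), where it stood at 861 ± 178 and 656 ± 177 CPM. So did Il1rn (-3.17, SE 0.58), at 154 ± 66.3 and 96.2 ± 39.4 CPM. The NF-kB genes Bcl3 (-2.65, SE 0.42) and Tnip3 (-2.63, SE 0.47), the scavenger receptor gene Cd36 (-2.04, SE 0.33), the vitamin D receptor gene Vdr (-4.99, SE 0.81) and H2-Aa (-1.17, SE 0.24) likewise had a lower response in DM. The chemokine gene Ccl6 had a higher one (1.96, SE 0.34, adjusted p = 0.0228), with 195 ± 74.9 and 491 ± 126 CPM in DM and 78 ± 9.83 and 50.6 ± 6.69 CPM in MG. So had the cytokine gene Il27 (7.19, SE 1.33), which stood at 0.0284 ± 0.0492 and 3.96 ± 2.73 CPM in DM and at 4.03 ± 0.553 and 3.53 ± 0.4 CPM in MG.

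Called in the fit to all libraries but not in the weighted fit were higher responses in DM of the protease inhibitor gene Serpine2 (2.49, SE 0.33, adjusted p = 0.00677), Hist1h2ac, Bid, Herc6, Igtp, Psmb10 and Irgm2. The same held for lower responses of Sall1, Tgfa, Nav3, Adam33, Siglech, Gas6, Dab2, Stab1, Ciita, Casp4, Clec4e, C5ar1, C3ar1 and Cd244a. The differences of P2ry12 (0.07, SE 0.38), Tmem119 (0.23, SE 0.41), Cx3cr1 (-0.11, SE 0.28), Mrc1 (-1.13, SE 0.33, adjusted p = 0.157) and Lyve1 (0.64, SE 0.95) did not pass. The count of 112 was 19, 9 and 30 without MG control 1, 2 and 3, and 54, 43 and 35 without MG infected 1, 2 and 3. It was 59 without DM control 2, 202 and 257 without DM infected 2 and 3, and 941, with 99 of the 112 among them, without DM infected 1 and 3 together.

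By list, 0 of 30 type I interferon response genes and 0 of 30 cell cycle genes differed in response (1 lower and 1 higher, respectively, adjusted over the list alone). Of 17 MHC class I genes Psmb10 passed, and 12 had a higher and 1 a lower response in DM adjusted over the list alone (list adjusted p = 1.36e-09, and 0.38 with an estimated correlation). Of 19 interferon gamma response genes Igtp and Irgm2 passed (3 adjusted over the list alone). Lower responses in DM passed for 2 of 10 MHC class II genes (5 adjusted over the list alone), 3 of 20 border macrophage genes (8) and 5 of 24 complement genes (8, with 1 higher). They passed for 2 of 18 microglia identity genes (3) and 2 of 20 NF-kB genes (3). In the weighted fit lower responses passed for 1 MHC class II, 2 complement and 2 NF-kB genes, and 0 genes passed among the type I interferon response, cell cycle, MHC class I, interferon gamma response, border macrophage and microglia identity genes. Of the 12 lists called, microglia identity and immediate early genes lost their call in the weighted fit (adjusted p = 0.1305 and 0.376). With an estimated correlation 0 of the 12 held, where the lowest adjusted p was 0.38.

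**Figure D4:**
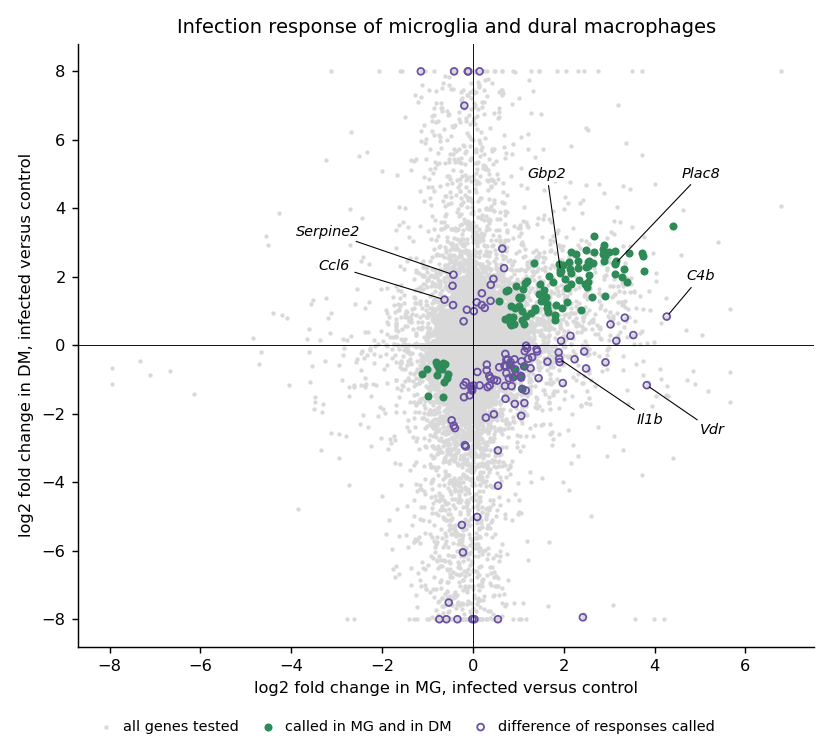
Log2 fold change after infection in DM against that in MG, with 1 grey point per gene tested, filled green points for genes called in both populations and open purple circles for genes whose responses differed. Axes end at 8 on either side, with 98 genes beyond them drawn at the limit, and 90 of the 112 circles lie where the response was lower in DM.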

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

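All tests of the cell cycle and of the lower responses in DM, and the test of listed cell types for the microglia genes, were chosen after the result was seen. Groups of 3 libraries are too small for a test of single libraries. Each gene and list flagged next is therefore a difference of the infection response between DM and MG that passed the interaction test. Values are DM minus MG on the log2 scale. Of the patterns weighed after them, those of microglia identity and cell cycle genes are changes within a population and were not taken from the interaction test.

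Higher responses in DM were those of Serpine2 (2.49), Hist1h2ac (2.189), Ccl6 (1.96), Bid (1.61), Herc6 (1.57) and Igtp (1.49). Lower responses were those of Tgfa (-5.00), Vdr (-4.99), Nav3 (-4.65), Adam33 (-3.62) and C4b (-3.43). For Sall1 the fitted difference was -9.43, but since infected DM held 0 counts of Sall1 this value depends on the prior count and is no bound. Of these 12 genes Ccl6, Vdr and C4b were also called in the weighted fit.

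The lists whose responses differed at the preset correlation had lower medians in DM for microglia identity (-0.42), border macrophage identity (-0.98), MHC class II (-0.68), NF-kB targets (-0.35), complement and phagocytic receptors (-0.26) and immediate early genes (-0.24). They had higher medians for MHC class I (0.68), interferon gamma response (0.41), glycolysis and hypoxia (0.28), oxidative phosphorylation (0.39) and cytosolic ribosomal proteins (0.14). The erythroid markers had a median of 4.22, which rests on fitted values of genes at 0 in whole groups. With an estimated correlation 0 of these 12 lists were called.

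The first pattern weighed was the lower level of microglia identity genes in infected MG. The list's median stayed at or below -0.346 under RLE scaling, upper-quartile scaling and without ribosomal RNA-like features, against -0.36 as reported. The choice among these scalings was thus not the cause. All of them take most genes as unchanged, so an error that they share, such as from a change in total RNA, is not excluded. To give the list's median, other cells would need to bring 21.8% of the RNA. Against dural macrophages stands that Lyz2, Cd74 and MHC class II transcripts rose by at most 173 CPM in an infected MG library, with 16500 CPM in DM. The border macrophage identity genes do not decide, since their sum was lower in each infected MG library than in the controls. Their mean log2 level was 2.319, 2.682 and 2.618 in infected MG 1, 2 and 3, against 2.355 to 2.376 in the controls. Dilution by cells of other types as a part of the cause cannot be told apart from lower expression, since the largest rise of their marker lists, 177 CPM of monocyte markers, has no library of pure cells to set it against. As the whole cause, it would lower all genes that those cells lack by the same factor. The list's quartiles lay at -0.582 and -0.18, and mean P2ry12 fell further than mean Tmem119 or Cx3cr1. These unequal falls argue against dilution as the whole cause. The median of 35 other genes at least 64-fold higher in MG than in DM lay below that of the list, at -0.56. The differences were -0.109, -0.157 and -0.347 in infected MG 1, 2 and 3. To give the median of these 35 genes, other cells would need to bring 32.2% of the RNA. A state of infected microglia that lowers such genes stays open as the untested biological explanation.

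The second pattern was the higher level of cell cycle genes. In infected MG the summed Mpo, Elane and Prtn3 reached at most 5.35 CPM, against a mean rise of 160 CPM of summed Mki67 and Top2a, which argues against granulocyte precursors. Dural macrophages would have brought their Lyz2 and MHC class II transcripts, of which the libraries showed at most 3.62% of the rise needed. The rise needed was taken from the ratio of these transcripts to Mki67 in whole infected DM libraries. This argues against cells with that ratio, but cells with a larger dividing share, or with fewer of these transcripts, would bring less and are not excluded. T and NK cell markers summed to 116, 115 and 54.2 CPM in infected MG 1, 2 and 3, against 74.1 to 79.3 CPM in the controls. The sum was thus lowest in infected MG 3, which held the most Mki67, but it was raised in infected MG 1 and 2. Dividing T and NK cells and dividing monocytes were not tested and stay open beside dividing microglia. In infected DM the list's median was 1.263 without DM infected 1 and 3, with 8 of 30 genes called, and since this leaves 1 infected DM library, granulocyte precursors and dividing macrophages cannot be told apart there.

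The third pattern was that 90 of the 112 differences were lower responses in DM than in MG. Unequal spread between the populations would predict that weights per library even out the directions, but 81.8% of the 44 genes called with weights were lower (exact 95% interval 67.3 to 91.8%). Of these 44 genes 40 were among the 112, and the interval takes genes as independent, so unequal spread is not excluded. Lower were 434 of 615 genes called with DESeq2 and 44 of 67 called with limma-voom without weights. A limited room for further rise of transcripts already high in DM cannot be told apart from a different response. Of the 90 genes 80% stood higher in DM than in MG of control mice and 57.8% (46.9 to 68.1%) of infected mice, against 47.3% and 47.7% of all genes, but the same libraries enter the difference of responses, which by itself raises the first share and lowers the second. Of the 90 genes 37 rose in MG and 58 fell in DM, 6 of them both, so that lower responses in DM were not of 1 kind.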

How the results depend on the processing

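The fits without DM infected 1 and 3, the fit without ribosomal RNA-like features, and for the lists and the correlation also leave-one-out and the second fit, were chosen after seeing the data. Where a cause is not named, the cause was not tested.

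Between the populations, counts stayed within 1.5 times those reported under every alternative run: 4964 to 9432 genes in control mice, against 7284, and 5241 to 8743 in infected mice, against 7603. For infection, RLE and upper-quartile scaling, both filters and the removal of ribosomal RNA-like features gave 248 to 315 genes in MG and 1279 to 1592 in DM.

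In MG, where 258 genes were called, DESeq2 called 568, limma-voom 142, limma-voom with sample weights 2396, glmTreat 106 and the fit to the 2 groups 1811, and leave-one-out gave 97 to 338. In DM, where 1529 were called, they gave 2826 for DESeq2, 131 with sample weights, 284 for glmTreat and 355 for the 2 groups, and leave-one-out gave 963 to 1995. Weights and the 2-group fit use a spread closer to each population's own, which is smaller in MG and larger in DM, and glmTreat asks for a larger change. In both populations the fewest genes in leave-one-out were called in the fit without MG control 2.

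For the difference of responses, with 112 genes, DESeq2 called 615, limma-voom 67, sample weights 44, glmTreat 27 and the fit without DM infected 1 and 3 941, and leave-one-out gave 9 (without MG control 2) to 257 (without DM infected 3). With a replicate block 58 genes were called, and 31 with a block by mouse. Residuals of libraries with the same number correlated at -0.013 to 0.031 between MG and DM and at -0.088 to 0.028 between control and infected mice. With 3 libraries per group and different cells in brain and dura, such values do not settle whether a shared number marks a shared mouse.

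Of the lists, with an estimated correlation 3 of 11 were called in MG, 1 of 16 in DM, 1 of 25 and 8 of 26 between the populations in control and infected mice, and 0 of 12 for the difference of responses. With fry 5 were called in MG and 0 for the difference, and without DM infected 1 and 3 5 for the difference, where leave-one-out gave 7 to 15. The correlation of the responses, 0.145, was 0.351 over genes with a mean CPM of at least 10, 0.098 without DM infected 1 and 3, and 0.101 to 0.15 in leave-one-out.

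Directions turned in 4 places. Without DM infected 1 and 3, fibroblast markers were higher in infected DM (adjusted p = 0.0194, from 6.8e-05 to 0.466 under the other list tests and fits), and the microglia identity list turned to a higher response in DM (adjusted p = 0.783, from 0.00308 to 0.572 under the others). The globin gene Hba-a1, not called in DM against MG of control mice (log2 fold change 3.36), ran in leave-one-out from -7.245 without DM control 1, a fitted value against a group at 0, to 3.92. Slc17a7, not called in infected mice (2.64), ran from -3.43 without DM infected 2 to 3.23, and was called at 4.17 without DM infected 1 and 3. Those single libraries held nearly all counts of these genes in their group. Both genes were also negative, without a call, with limma-voom (-1.71 and -0.37), sample weights (-1.31 and -0.42) and the replicate block by mouse (-2.45 and -0.92).

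In other splits of the libraries, 10 splits of 6 libraries are too few for a share under 0.05. As many genes were called in 1 of 10 splits, the real one, for MG (258, highest other 0), 1 for DM (1529, highest other 12), 1 for control mice (7284, highest other 0) and 1 for infected mice (7603, highest other 0). As many lists were called at the preset correlation in 7 of 10 splits for MG (11, highest other 18), 4 for DM (16, highest other 17), 1 for control mice (25, highest other 24) and 2 for infected mice (26, highest other 26). With an estimated correlation the highest other split called 4 lists in MG, above the real 3, and 0 in each of the other 3 comparisons. For the difference of responses 2 of 100 splits called as many genes (112, highest other 1164), and the other split exchanges control and infected in DM and so tests the sum of the responses. The remaining splits mix control and infected libraries, so that infection effects enter their spread, and chance is not excluded by this share. Nor was chance excluded for its lists, with as many in 22 of 100 splits (12, highest other 15).

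Depth limits genes of low level, since 3 counts in the shallowest library, DM infected 1, correspond to 0.291 CPM.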
